A study of Saccharomyces cerevisiae and Nakaseomyces glabratus and Naumovozyma castellii with 205 samples.

How the data were processed

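Total RNA of yeast cultures was measured on 205 Agilent arrays with 2 colours, in 8 species and 18 time courses, each course being 1 species under 1 stress. Per the labels, every array carries RNA of a stressed culture in Cy5 and RNA of an unstressed culture taken at time 0 in Cy3, normally of the same biological replicate; in the C. albicans H2O2 course the arrays of replicate B carry the time 0 RNA of replicate A. Labels put no array in the opposite dye orientation. A positive log2 value therefore stands for more mRNA in the stressed culture, and a gene-specific dye effect cannot be separated from a change against time 0, whereas one that is constant for a probe cancels in the difference between time points or treatments. S. cerevisiae NaCl replicates A and B are on another array design than replicate C and the H2O2 and heat arrays, and both designs hold the same 6256 probes by name, with other numbers of spots. Biological replicates carry letters in the labels, and technical replicates of a culture and time were averaged first and counted as 1 replicate. The labels give NaCl at 0.3 M and H2O2 at 5 mM, both from 30 °C, and heat as a move from 22 °C to pre-warmed medium at 37 or 42 °C, without saying which species got which temperature.

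Spot intensity values were produced by Agilent Feature Extraction, per the file headers in version 10.5.1.1 on 161 arrays, 10.1.1.1 on 28 and 9.5.1.1 on 16; the submitters' processing notes name version 10.5.1.1. On 12 arrays the files hold a median signal per spot where the others hold a mean, and the median was used there. The tables of log2 values deposited by the authors for the whole series hold ratios of stressed over time 0 signal. Their scale and direction were taken from the S. cerevisiae arrays, whose columns correlate across genes with the log ratios of the same array (lowest r 0.982 for NaCl, 0.983 for heat and 0.438 for H2O2), and on other designs from matching quantiles. Column medians lie between -0.372 and 0.103, and up to 53.3% of a column are exact zeros, which were taken as no value. Whether the authors centred these values, how they combined probes and how they treated zeros is not given in the sources used here. These tables served only as an alternative. Array slides number 36 and array designs 9.

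Mean and background median signals of each channel were corrected with normexp (offset 50) and normalized within each array by loess in limma 3.58.1 (R 4.3.3, with data.table version 1.17.8, statmod 1.5.0 and jsonlite 2.0.0). On 13 of 205 arrays, 1 of them at 15 min, a few spots with an extreme local background upset the normexp fit. Its background SD passed 100 in a channel there (up to 18091), and the log2 ratios came out too narrow. In N. castellii heat replicate A at 60 min, for example, their SD was 0.757, against 1.28 in the deposited tables. This was found after the results were seen, and the values were left as processed. As an added alternative, a local background over 10 times the median of its channel was replaced by that median, at most 31 spots in a channel of such an array. No array then passed that SD, and in the example the SD of the ratios was 1.20. Of the counts against time 0, 0 of 18 at 15 min and 8 of 61 at other times moved by more than 1.5 times. Control spots had weight 0 in loess and were left out afterwards, as were spots with outlier flags. Spots of a probe and then probes of a gene were averaged; probes of a gene correlated at r = 0.901 to 0.993 across genes within a course. A probe counted as above background where at least 50% of its spots did, and a gene was kept where it was above background in either channel on at least 50% of a course's arrays. Where all probes of a gene were below background in a channel on every array of a group, the change is given as "at least N-fold": the bright group's mean against the dim group's mean of the higher of the gene's own signal and, per array, the lowest signal among probes above background, per channel after loess and Aquantile scaling, a bound open to dye bias.

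For each course limma's lmFit and eBayes were fitted to the log2 ratios with a mean per time point, so that all time points share 1 estimate of the spread. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 with at least a 2-fold mean change. The same fit gave the contrast of 60 against 15 min. For species with more than 1 treatment, a fit over all arrays of the species gave the moderated F-test and pairwise contrasts between treatments at 15 min. Chosen before the data were examined were these tests, the 19 gene lists, a panel of 25 marker genes and all alternatives except those named as added later.

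Gene lists were tested with camera at its preset correlation of 0.01, adjusted over all lists and courses at 15 min, and again with an estimated correlation; a list needed 5 measured members. The lists cover ribosomal proteins, ribosome biogenesis, RNA polymerase I and III, chaperones, general stress genes, trehalose and glycogen, glycerol and ion homeostasis, antioxidants, the pentose phosphate pathway, the proteasome, respiration with the TCA cycle, the mitochondrial ribosome, glycolysis, amino acid biosynthesis, sulphur assimilation, ergosterol synthesis, histones, the iron regulon and autophagy. Lists were used in S. cerevisiae alone, because the files do not pair the identifiers of the other species with names; for the same reason no correlation of responses across species was made. Of 6256 S. cerevisiae genes on the arrays, 5756 matched the R64 reference table by locus tag, which changed 1290 symbols from those of the array design. No genome build is named in the files, so no coordinates are given. Genes named in the text are, per course at 15 min, those with the largest change each way among called genes that moved the same way in every replicate (8 each way in S. cerevisiae, at most 2 identifiers each way elsewhere), the marker panel, 2 to 4 members of a list with the largest change in the list's direction, and the 4 genes each way with the largest difference between treatments.

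The fit, the thresholds and the list test were tested on simulated log2 ratios, with 100 genes changed 2-fold and 100 changed 4-fold among the genes of a course. Background correction and loess were not part of this test. At 15 min the adjusted p found 98% of the 2-fold genes for S. cerevisiae NaCl (5668 genes), 87% for H2O2 (5482 genes) and 92% for heat (5596 genes); with the fold threshold added these became 59%, 51% and 53%. Of the 4-fold genes, 99%, 98% and 96% were called in these courses. Among all genes that passed the adjusted p, without the fold threshold, 2.48%, 3.14% and 3.09% were false. For N. castellii NaCl (5239 genes), N. glabratus NaCl (5100 genes) and C. albicans NaCl (5425 genes) the 4-fold genes were called at 99%, 100% and 93%. Of the genes that passed the adjusted p there, 4.55%, 4.88% and 5.82% were false. Of 200 random lists per course, at most 1% fell under an unadjusted p of 0.05 in camera. Simulated genes varied independently, so this could not show false list calls that arise from correlation between the genes of a list.

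Counts at 15 min, counts of genes that differ between 60 and 15 min or between treatments (F-test), gene lists at 15 min and named genes were recomputed with the scanner software's processed signals, with median centring in place of loess, with no filter on dim probes, with the deposited tables of the whole series, with replicate or slide as a random block, without each replicate in turn, and, for counts at 15 min, with no fold threshold, with each probe on its own and with a single array design or the design as a block. Replicate as a fixed block was run for 60 against 15 min. Added after the data were seen were runs without dim arrays, on arrays of 1 slide only, with replicate A of the NaCl arrays labelled L. waltii turned, with exchanged time labels, without a technical replicate of S. japonicus, without the 45 min arrays of 1 N. glabratus culture, with extreme local backgrounds replaced, and camera at the other time points. Counts and lists at the other time points were recomputed with extreme local backgrounds replaced only. Counts and lists between pairs of treatments were recomputed so, with the slide as a random block and on S. cerevisiae arrays of 1 design, also added after the data were seen. In courses with under 3 replicates at 15 min, leaving out a replicate took out its 15 min array alone. For 60 against 15 min it took out the arrays of these times. The replicate's other arrays stayed in the fit and helped to set the spread. For counts between treatments the whole replicate was left out. Where leaving out a replicate left 1 array in a group, that array was assumed to vary like the other groups. Replicate letters come from the labels, which set stressed and time 0 RNA of the same letter on each array. Correlations between time points of the deviations of same-lettered arrays from their group means lay above 0.1 for every pair in C. albicans NaCl among the courses with at least 3 replicates (lowest r 0.339), and went as low as -0.954 in N. glabratus H2O2.

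Signal set the depth: the median array had 94.4% of its probes above background in green and 95.5% in red. On 7 arrays under 50% of the probes passed in at least 1 channel. At most 0.0846% of spots were saturated, and 0% to 15.6% of spots carried outlier flags. The number of arrays limits the precision of every value. Growth-curve samples that the series' design text mentions are not analysed here.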

Results

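mRNA levels were followed in 8 yeast species after salt (0.3 M NaCl), hydrogen peroxide (5 mM H2O2) or a heat shock, in order to compare how gene expression programs respond to stress in related yeasts. The 205 arrays form 18 time courses with samples at 5, 15, 30 and 60 min, and for heat also at 45 min except in Schizosaccharomyces pombe. At 15 min, the time used for the main comparison, S. cerevisiae has 3 replicates for NaCl, 5 for H2O2 and 2 for heat, Naumovozyma castellii 3, 3 and 2, Nakaseomyces glabratus (formerly Candida glabrata) 4, 3 and 2, and Candida albicans 3, 2 and 2. Kluyveromyces lactis has 2 for H2O2 and 2 for heat, Lachancea waltii 4 arrays so labelled for NaCl and 2 for heat, and S. pombe and Schizosaccharomyces japonicus 2 each for heat. Values are log2 ratios of stressed over time 0 signal, given as mean ± SD over biological replicates, and "rose" or "fell" is written of genes with an adjusted p under 0.05 in limma and at least a 2-fold change. By the labels the dyes were never exchanged, so that a gene-specific dye effect remains inside changes against time 0. On 13 arrays, 1 of them at 15 min, a few extreme local backgrounds upset the background correction and narrowed the ratios. Values stand as processed, and counts with these backgrounds replaced follow where they differ by more than 1.5 times.

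In S. cerevisiae 15 min after NaCl, most general stress genes and trehalose and glycogen genes rose and most ribosome biogenesis genes fell. HSP12, which encodes a small membrane-stabilizing heat shock protein, had a fitted value of 10.70 ± 0.58 (n = 3) and rose at least 1285-fold, its time 0 signal not being above background. STL1, the glycerol symporter of the plasma membrane, had 9.06 ± 0.33 (at least 437-fold), CTT1, the cytosolic catalase, 8.51 ± 0.43 and ALD3, an aldehyde dehydrogenase, 8.58 ± 0.44. Also among the 8 largest rises were RTC3 (8.84 ± 0.23), PHM7 (8.14 ± 0.31), FMP48 (at least 374-fold) and YNL194C (at least 200.4-fold). The largest falls were those of PHO84, the high-affinity phosphate transporter (-5.27 ± 0.08), and NSR1, a nucleolar protein of pre-rRNA processing (-4.72 ± 0.18). SFG1 (-4.27 ± 0.41), the pre-ribosome GTPase gene NOG2 (-4.22 ± 0.33), the copper transporter gene CTR3 (-4.05 ± 0.57), the ribosome assembly gene RRS1 (-3.93 ± 0.05), the polyamine exporter gene TPO2 (-3.93 ± 0.10) and YGR079W (at least 14.5-fold lower) followed. In all, 1492 of 5672 genes changed, 847 up and 645 down (limma), and the adjusted p of the genes named here was at most 6.14e-06.

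Of 61 measured general stress genes 57 rose and 0 fell after NaCl, with a median of 4.62 (camera, adjusted p = 3.90e-16, but adjusted p = 0.483 with an estimated correlation). Here and in what follows, counts adjusted over the list alone were the same unless another is given. The glycerol and ion homeostasis genes had a median of 0.91 and 13 of 27 rose while 2 fell (adjusted p = 2.50e-04; adjusted p = 0.281 with an estimated correlation); among them were the glycerol-phosphatase genes GPP2 (7.03 ± 0.11) and GPP1 (3.35 ± 0.27), the glycerol-3-phosphate dehydrogenase gene GPD1 (6.51 ± 0.27) and the sodium pump gene ENA1 (6.50 ± 0.17). Of the trehalose and glycogen genes 19 of 22 rose, with a median of 3.41 (adjusted p = 1.09e-06; adjusted p = 0.483 with an estimated correlation), including TPS1 (5.83 ± 0.15), TSL1 (5.78 ± 0.12) and TPS2 (5.62 ± 0.28) of the trehalose synthase complex. Chaperone genes had a median of 1.56, with 21 of 40 up and 3 down (adjusted p = 2.18e-04; adjusted p = 0.508 with an estimated correlation), led by HSP42 (6.45 ± 0.76) and SSA4 (6.26 ± 0.30). Of the antioxidant genes 15 of 45 rose and 1 fell (median 0.52, adjusted p = 0.00450; adjusted p = 0.471 with an estimated correlation), with GRE2, a methylglyoxal reductase gene, at 6.48 ± 0.14 and PRX1, a mitochondrial peroxiredoxin gene, at 3.05 ± 0.14. In the pentose phosphate pathway 7 of 13 genes rose and 1 fell (median 1.31, adjusted p = 0.0354; adjusted p = 0.508 with an estimated correlation), among them the minor transketolase gene TKL2 (7.53 ± 0.38), SOL4 (7.11 ± 0.19) and the transaldolase gene NQM1 (at least 99.2-fold). Shifts upward were also called for respiration and the TCA cycle (15 of 46 up, median 0.56, adjusted p = 3.96e-05; citrate synthase gene CIT1 2.60 ± 0.08), glycolysis (10 of 17 up, median 1.15, adjusted p = 0.00632; TDH3 2.41 ± 0.22), autophagy (11 of 22 up, median 0.93, adjusted p = 1.86e-04; ATG8 3.57 ± 0.30) and the proteasome (0 of 42 members at 2-fold, median 0.49, adjusted p = 1.86e-04). With an estimated correlation these had adjusted p = 0.508, 0.508, 0.281 and 0.508.

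Of 138 ribosome biogenesis genes 134 fell and 0 rose after NaCl, with a median of -2.10 (camera, adjusted p = 1.12e-34; adjusted p = 0.281 with an estimated correlation). Subunits and factors of RNA polymerase I and III fell in 18 of 26 cases (median -1.21, adjusted p = 1.22e-08; adjusted p = 0.281 with an estimated correlation), with RPA43 at -2.95 ± 0.09. Ribosomal protein genes themselves had a median of -0.21, with 10 of 137 down and 1 up (adjusted p = 0.00508; adjusted p = 0.796 with an estimated correlation), and those that fell most were RPS9A (-3.33 ± 0.07), RPL22B (-3.18 ± 0.17) and RPL7B (-2.75 ± 0.09). Amino acid biosynthesis genes had a median of -0.20 and 8 of 62 fell (adjusted p = 0.00581; adjusted p = 0.508 with an estimated correlation), for example LEU9 (-2.00 ± 0.03) of leucine synthesis and ILV5 (-1.82 ± 0.13) of branched-chain synthesis. Not called were the lists of sulphur assimilation (2 up, 5 down of 25; methionine permease gene MUP1 -1.55 ± 0.10), ergosterol synthesis (2 of 25 down; ERG3 -1.79 ± 0.33), histones (0 of 11 at 2-fold, HTA1 -0.79 ± 0.05), the iron regulon (5 up and 8 down of 24; the ferric reductase gene FRE1 -3.76 ± 0.22) and the mitochondrial ribosome (0 of 66 at 2-fold, median -0.02). Without replicate A the ergosterol list reached adjusted p = 0.0429. Median centring in place of loess ended the calls of the ribosomal proteins (adjusted p = 0.132) and the proteasome (adjusted p = 0.110), and the deposited tables ended that of glycolysis (adjusted p = 0.499).

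In NaCl many chaperone genes and most general stress genes were lower at 60 than at 15 min, while most sulphur assimilation genes were higher. These are counts of genes, and the lists were not tested for this difference. Between 15 and 60 min 714 genes differed in limma, 287 higher and 427 lower at 60 min, against 463 with median centring. Lower at 60 min were 21 of 40 chaperone genes (median 1.56 at 15 min and -0.02 at 60 min), 39 of 61 general stress genes (4.62 and 3.05), 15 of 22 trehalose and glycogen genes (3.41 and 2.03) and 8 of 27 glycerol and ion homeostasis genes, with 0 higher in each list. HSP104, the disaggregase gene, had 4.68 at 15 min and 0.63 at 60 min, GPD1 6.51 and 2.63, GPP1 3.35 and 0.48, and ENA1 6.50 and 2.76. Of the 25 markers 14 were lower at 60 min and 0 higher. Higher at 60 min were 16 of 25 sulphur assimilation genes (median -0.30 and 1.42), 12 of 62 amino acid biosynthesis genes and 6 of 46 respiration genes. For ribosome biogenesis 7 were higher and 16 lower (median -2.10 and -2.41). At 5 min 112 genes had changed, 111 of them up, and 24 of 61 general stress genes had risen (30 adjusted over the list alone; median 0.99, with replicate medians from 0.16 to 2.04). With extreme local backgrounds replaced it was 344 genes (309 up, 35 down) and 47 general stress genes (median 2.15, with replicate medians from 2.04 to 2.26). At 30 min 1627 and at 60 min 1201 genes had changed.

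**Figure D1:**
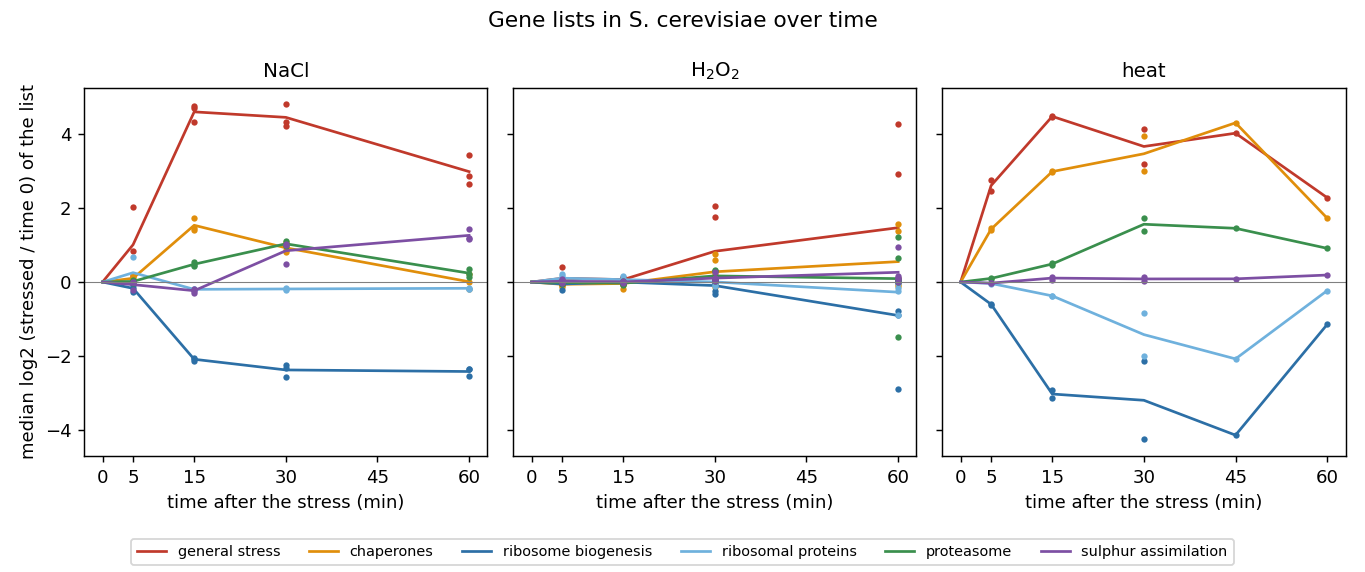
Median log2 ratio of stressed over time 0 signal (vertical axis) of 6 gene lists in S. cerevisiae against the minutes after NaCl, H2O2 or heat (horizontal axis), with biological replicates as points (1 in heat at 45 and 60 min) and lines that join their means and start at 0 by definition. General stress genes reach a median of 4.62 in NaCl and 4.53 in heat at 15 min, ribosome biogenesis genes -2.10 and -3.04, and in H2O2 replicates separate at 30 and 60 min; NaCl replicates B and C at 5 min have an upset background correction.

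In H2O2 the S. cerevisiae transcriptome had moved little at 15 min: 3 of 5482 genes rose and 0 fell (limma; 330 genes at an unadjusted p under 0.05). These were TDH3, a glyceraldehyde-3-phosphate dehydrogenase gene (1.43 ± 0.16, 1.20 to 1.58 over n = 5, adjusted p = 0.00135), the cell wall protein gene CCW12 (1.35 ± 0.29, adjusted p = 0.0197) and the enolase gene ENO2 (1.07 ± 0.19, adjusted p = 0.0280). Their values were above 0 in 5 of 5 replicates, and without dye swaps a dye effect on these genes cannot be separated from a change. The SD of log2 ratios over all genes was 0.11 to 0.30 on the 15 min arrays, and up to 1.54 at 60 min. All time points share 1 spread, which the differing 60 min replicates widen, so genes may have been missed at 15 min. A fit with the spread of the 15 min arrays alone was not run. Of 24 measured markers 0 rose and 0 fell. SRX1, which encodes the sulfiredoxin that repairs oxidized peroxiredoxins, had 1.18 ± 1.41 with replicates from 0.06 to 2.82, and CTT1 had a mean of -0.00 ± 0.22. In the glycolysis list 2 of 17 genes rose (median 0.38, adjusted p = 5.52e-09; adjusted p = 0.281 with an estimated correlation), and PDC1, the pyruvate decarboxylase gene, had 0.98 ± 0.27. No member at 2-fold was found in the other lists called by camera: ribosomal proteins (median 0.06, adjusted p = 6.24e-06), amino acid biosynthesis (0.04, adjusted p = 0.0230), RNA polymerase I and III (-0.12, adjusted p = 0.0366), the mitochondrial ribosome (-0.10, adjusted p = 1.25e-05) and histones (-0.26, adjusted p = 0.00413). With an estimated correlation these had adjusted p = 0.508, 0.626, 0.705, 0.483 and 0.483. The remaining 13 lists, general stress (0 of 58 at 2-fold, median 0.07), chaperones (0 of 38, -0.04) and antioxidants (0 of 44, 0.04) among them, were not called (adjusted p from 0.260 to 0.923), and for ribosome biogenesis, the proteasome and autophagy the median (-0.02, -0.01 and -0.06) lies below 0 while the test points up.

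Several of these calls hang on a setting. Without replicate A limma called 0 genes, without B or D 1 (TDH3; CCW12 and ENO2 also lost their calls without F), and with median centring 1, while runs without dim arrays called 6. Rises made up 100% of calls, and 50% or 33.3% with processed signals or the deposited tables, where CCW12 and ENO2 were not called. The ribosomal protein median turned to -0.01 with processed signals (adjusted p = 0.847) and was not called from the deposited tables (adjusted p = 0.665), the histone median turned to 0.13 with median centring (adjusted p = 0.257), and the RNA polymerase call was lost without replicate D (adjusted p = 0.0795) and the amino acid call without A (adjusted p = 0.0771) or E (adjusted p = 0.0582). Median centring brought the pentose phosphate list to adjusted p = 0.0476. Over 13 settings the ribosomal protein median ran from -0.03 to 0.59, with a lowest adjusted p of 1.53e-37 in camera. The glycolysis median ran from 0.25 to 0.90, so the size of both shifts depends on the setting.

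By 60 min in H2O2 most general stress genes and some antioxidant genes had risen in the mean of the S. cerevisiae replicates. Single replicates differed widely. With extreme local backgrounds replaced, their medians ran from 0.03 to 4.28 for general stress and from -0.33 to 2.03 for antioxidants. SRX1 reached 4.63 ± 3.99, the NADPH oxidoreductase gene OYE3 3.62 ± 3.54, the peroxiredoxin gene TSA2 2.47 ± 3.29, DDR2 3.74 ± 3.85 and HSP12 3.59 ± 4.47, all called in limma with n = 5. TRX2 (1.39) and TRR1 (0.77) were not called. Calls at 60 min, here and in the counts below, assume 1 spread shared by all time points. HSP12, below background on most 15 min arrays, had an SD of 0.08 at 15 min and 4.47 at 60 min. A fit with the spread of the 60 min arrays alone was not run, so these calls are uncertain. Between 60 and 15 min limma called none of the genes named here (lowest adjusted p = 0.137, OYE3). Of 58 general stress genes 41 rose (48 adjusted over the list alone; median 1.58, adjusted p = 2.51e-12; adjusted p = 0.512 with an estimated correlation), and 56 of 138 ribosome biogenesis genes fell (median -0.91, adjusted p = 1.32e-18; adjusted p = 0.509 with an estimated correlation). Trehalose and glycogen genes rose in 11 of 21 cases, chaperones in 12 of 38 (15 adjusted over the list alone), antioxidants in 11 of 44 (12 adjusted over the list alone; 2 fell; median 0.66, adjusted p = 0.00214; adjusted p = 0.643 with an estimated correlation) and glycolysis genes in 7 of 17. The 586 called genes (367 up, 219 down) included 312 that moved the same way in every replicate: the SD of log2 ratios over all genes stayed at or below 0.32 at every time in replicates A and B, and reached 1.09 to 1.54 in D, E and F. The 60 min array of D was dim, with 48.9% of its red probes above background. Across genes it correlated at r = 0.180 with F and 0.254 with E, against 0.846 between E and F. At 5 min 2 genes and at 30 min 16 genes were called, or 1 and 30 with extreme local backgrounds replaced. Between 60 and 15 min 0 genes differed in limma over all genes (1432 at an unadjusted p under 0.05; 1 without replicate D, 1 without dim arrays), while adjusted over the list alone 44 ribosome biogenesis genes were lower and 13 general stress genes higher at 60 min.

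Heat moved the largest part of the S. cerevisiae transcriptome at 15 min, with chaperone genes among the largest rises and ribosome biogenesis genes the largest falls. Besides HSP12 (9.23 ± 0.33, n = 2 here and below), the leading genes were SSA4 of the HSP70 family (9.06 ± 0.02), TMA10 (9.05 ± 0.11), the small heat shock protein genes HSP42 (8.76 ± 0.15) and HSP26 (8.63 ± 0.32), RTC3 (8.42), the decarboxylase gene ARO10 (7.78) and the mitochondrial disaggregase gene HSP78 (7.71). All 8 largest falls belong to genes of nucleolar or ribosome assembly factors: NSR1 (-6.33 ± 0.46), RLP24 (-5.10), NOP15 (-5.00), RPF2 (-4.93), ALB1 (-4.88), NIP7 (-4.86), MAK16 (-4.82) and BRX1 (-4.79). In all, 2019 of 5596 genes changed, 1107 up and 912 down, and the adjusted p of these 16 genes was at most 0.00338 (limma). Of the markers 19 rose and 2 fell among 24 measured; GPP1, which rose in NaCl, had 0.02 ± 0.06 in heat, and the fall of RPL3 (-2.31) lost its call without either replicate.

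Chaperone genes rose in 33 of 40 cases and fell in 5 (median 3.01, adjusted p = 3.36e-06; adjusted p = 0.508 with an estimated correlation), and general stress genes in 60 of 62 (median 4.53, adjusted p = 1.37e-15; adjusted p = 0.508 with an estimated correlation), among them DDR2 (7.37 ± 0.10). Trehalose and glycogen genes rose in 18 of 21 cases (median 3.84, adjusted p = 8.50e-07; adjusted p = 0.508 with an estimated correlation), with TSL1 at 6.91, the glycogen phosphorylase gene GPH1 at 6.60 and the phosphoglucomutase gene PGM2 at 5.49. The iron regulon list, whose genes serve iron uptake and sparing, had 12 of 24 up and 3 down (median 0.95, adjusted p = 0.00561; adjusted p = 0.356 with an estimated correlation), including the cell wall mannoprotein genes FIT2 (5.10 ± 0.15) and FIT3 (3.96 ± 0.20) and the heme oxygenase gene HMX1 (4.34 ± 0.01). Among antioxidants 23 of 45 rose and 3 fell (median 1.06, adjusted p = 0.00347; adjusted p = 0.281 with an estimated correlation), with GRE2 at 4.97 and the glutathione transferase gene GTT1 at 3.11. In the glycerol and ion homeostasis list 13 of 26 rose and 2 fell (median 0.97, adjusted p = 0.0366; adjusted p = 0.483 with an estimated correlation; adjusted p = 0.0544 from the deposited tables), with ENA1 at 6.65 and GPP2 at 4.90. Respiration and TCA cycle genes rose in 22 of 46 cases (median 0.85, adjusted p = 1.77e-05), led by CIT1 (3.79) and the isocitrate dehydrogenase gene IDH2 (3.49). Glycolysis genes rose in 8 of 17 (median 0.94, adjusted p = 0.0230; TDH1 3.69), pentose phosphate genes in 7 of 13 with 1 down (median 1.01, adjusted p = 0.00730; SOL4 at least 41.8-fold), autophagy genes in 10 of 22 (median 0.97, adjusted p = 1.20e-04; ATG8 4.44) and proteasome genes in 1 of 42 (RPN14, 1.26; median 0.50, adjusted p = 2.18e-04). With an estimated correlation these 5 lists had adjusted p = 0.624, 0.705, 0.356, 0.281 and 0.611.

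Ribosome biogenesis genes fell in 133 of 138 cases after heat (134 adjusted over the list alone; median -3.04, adjusted p = 2.46e-17; adjusted p = 0.582 with an estimated correlation). RNA polymerase I and III genes fell in 20 of 26 (21 adjusted over the list alone; median -1.85, adjusted p = 6.83e-06; adjusted p = 0.611 with an estimated correlation), with RPA43 at least 24.1-fold lower, RPA34 at -4.37 and RPA12 at -4.20. For ribosomal proteins 10 of 137 fell (4 adjusted over the list alone; median -0.38, adjusted p = 0.0297), among them RPS9A (-3.24) and RPL22B (-3.20); this call had adjusted p = 0.921 with an estimated correlation and was lost with processed signals (adjusted p = 0.285) and the deposited tables (adjusted p = 0.307). The mitochondrial ribosome list had 3 of 66 down (median -0.38, adjusted p = 1.71e-04; adjusted p = 0.705 with an estimated correlation; MRPL20 -1.25). Amino acid biosynthesis was not called (3 up and 16 down of 62) except with processed signals (adjusted p = 0.0490), although the glutamine synthetase gene GLN1 (-3.42) and ILV5 (-3.15) fell. Sulphur assimilation (2 up and 7 down of 24, with a median of 0.11 and a mean of -0.07; SAM3 -2.41), ergosterol synthesis (4 of 25 down; ERG3 -2.11) and histones (0 of 11 at 2-fold; HTA2 -0.88) were not called either.

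Later in the heat course, at 30 min, many ribosomal protein genes joined the fall and most proteasome genes rose. At 30 min 82 of 137 ribosomal protein genes had fallen and 2 had risen (median -1.45, with -2.01 in one replicate and -0.84 in the other; adjusted p = 1.35e-09; adjusted p = 0.627 with an estimated correlation), and 37 of 42 proteasome genes had risen (median 1.54, adjusted p = 4.41e-10; adjusted p = 0.508 with an estimated correlation). The ribosomal protein median was -2.08 at 45 min and -0.23 at 60 min, with 1 replicate each, and at 60 min 2 of these genes were down and 1 up (0 of either adjusted over the list alone). At 60 min there is 1 replicate, assumed to vary like the other time points. On that assumption 939 genes differed between 60 and 15 min, 357 higher and 582 lower at 60 min, against 536 with the replicate as a fixed block; without replicate B limma called 0, and without A there is no 60 min array. Lower at 60 min were 12 of 40 chaperone genes (15 adjusted over the list alone; 3 were higher; medians 3.01 and 1.73), 40 of 62 general stress genes (43 adjusted over the list alone; medians 4.53 and 2.29) and 13 of 21 trehalose and glycogen genes (15 adjusted over the list alone). HSP104 had 7.36 at 15 min and 3.14 at 60 min, CTT1 6.06 and 1.20, DDR2 7.37 and 1.69, and NSR1 -6.33 and -2.18. At 5 and 30 min 546 and 2037 genes had changed. The counts at 45 min (2230) and 60 min (821) rest on 1 replicate each, with the spread taken from the other time points.

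**Figure D2:**
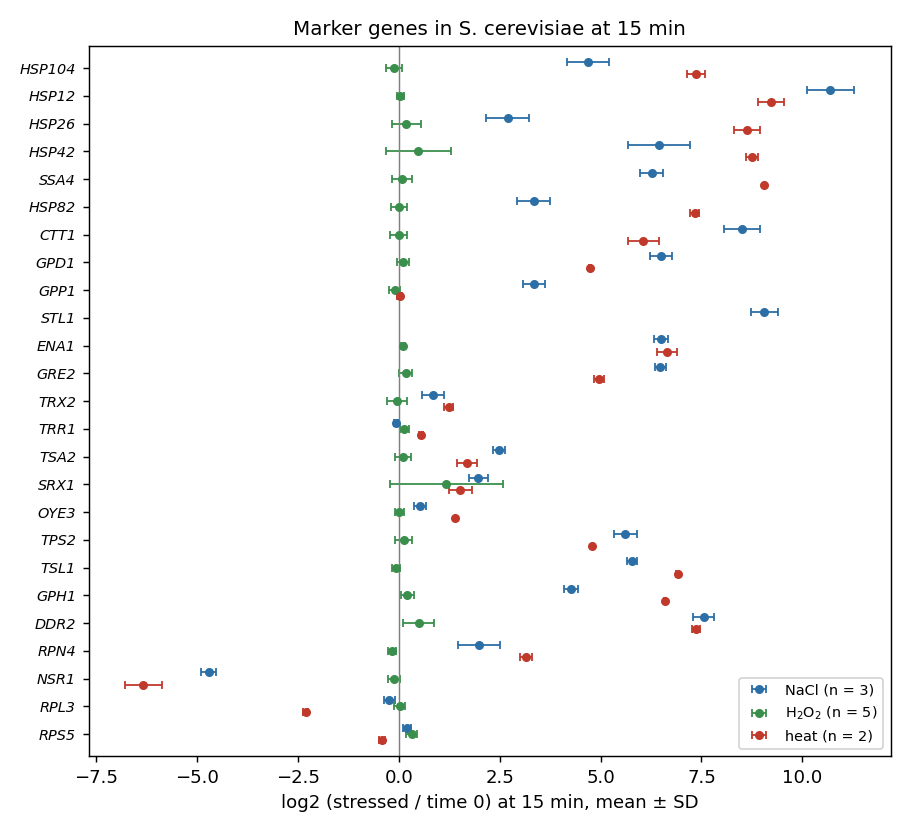
Log2 ratio of stressed over time 0 signal at 15 min (horizontal axis) of the marker genes (vertical axis) in S. cerevisiae, as mean and SD over biological replicates in NaCl (n = 3), H2O2 (n = 5) and heat (n = 2). GPP1 has 3.35 in NaCl and 0.02 in heat, SSA4 6.26 and 9.06, and SRX1 in H2O2 spans the widest SD of that treatment, 1.41; STL1 passed the filter in NaCl alone, where the values of HSP12, STL1 and OYE3 are fitted without time 0 signal above background.

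Tested directly, the 15 min responses of S. cerevisiae to salt and heat differed most in chaperone and iron regulon genes. Per the labels the time 0 cultures were at 30 °C for NaCl and H2O2 and at 22 °C for heat. In every species a contrast with heat therefore also holds any difference between these time 0 states, which cannot be told apart from the stress. Chaperone genes stood lower in NaCl than in heat (median difference -1.91, 16 of 38 lower and 1 higher, 17 and 1 adjusted over the list alone; adjusted p = 1.67e-08; adjusted p = 0.415 with an estimated correlation), and so did the iron regulon (-1.40, 13 of 24 lower and 1 higher, 14 and 1 adjusted over the list alone; adjusted p = 2.40e-11; adjusted p = 0.151 with an estimated correlation). Ribosome biogenesis genes fell less in NaCl (difference 0.94, 22 of 138 higher, 17 adjusted over the list alone; adjusted p = 1.39e-07; adjusted p = 0.805 with an estimated correlation). Also called were RNA polymerase I and III (0.62, adjusted p = 0.0251), respiration and the TCA cycle (-0.32, adjusted p = 0.00918) and the mitochondrial ribosome (0.32, adjusted p = 1.59e-04). With an estimated correlation these had adjusted p = 0.816, 0.816 and 0.527. FIT2 differed by -5.94 (-0.84 in NaCl and 5.10 in heat) and the autophagy gene ATG41 by -7.18 (-0.48 and 6.70), both measured on all arrays. In the other direction YHR033W differed by 4.56, with 1 time 0 array above background in each treatment. The proline oxidase gene PUT1 and ARO10 stood lower in NaCl, and the glucose transporter gene HXT1, FMP48 and YBR116C higher. Their sizes are not given, because in at least 1 treatment their time 0 signal was not above background on any array. In all, 495 of 5560 genes differed between NaCl and heat, 225 higher in NaCl and 270 higher in heat (limma). NaCl replicates A and B lie on another array design than all other S. cerevisiae arrays; without them, with 1 NaCl replicate left, 185 differed, and RNA polymerase I and III was not called (adjusted p = 0.0633).

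In each species the arrays of different treatments at 15 min lie on different slides. In S. cerevisiae each treatment spans at least 2 slides, and with the slide as a random block 482 genes differed between NaCl and heat, 1374 between NaCl and H2O2 and 1867 between H2O2 and heat. Against H2O2, 1382 genes differed in NaCl (780 higher in NaCl, 602 lower; 804 on the design with 1 NaCl replicate) and 1873 in heat (1022 higher in heat, 851 lower). HSP12, FMP48, ALD3 (8.70) and CTT1 (8.51) stood highest in NaCl over H2O2, and PHO84 (-5.37), NSR1 (-4.60), NOG2 (-4.16) and RRS1 (-3.93) lowest. No size is given for HSP12 and FMP48, whose time 0 signals were not above background on NaCl arrays, and their ranks follow fitted values. On H2O2 arrays FMP48 was in neither channel above background. Of 5 H2O2 arrays ALD3 was above it on 3 at time 0 and 2 under stress, and CTT1 on 2 and 2. For H2O2 over heat, NSR1 (6.21), RLP24 (4.94), NOP15 (4.88) and BRX1 (4.77) stood highest and HSP12 (-9.19), SSA4 (-8.98), TMA10 (-8.63) and HSP26 (-8.45) lowest. HSP12 and HSP26 were below background on most H2O2 arrays. At time 0 HSP12 was above it on 1 of 2 heat arrays, so its size and rank are uncertain. Of the 12 lists that camera called between NaCl and H2O2, glycerol and ion homeostasis kept its call with an estimated correlation (median difference 0.73, 11 higher and 2 lower of 25, adjusted p = 1.59e-04; adjusted p = 0.00541 with an estimated correlation). The other 11 had adjusted p between 0.415 and 0.865 with an estimated correlation, among them general stress (4.52, 57 higher) and ribosome biogenesis (-2.11, 132 lower). Between H2O2 and heat 13 lists were called, with adjusted p from 0.176 to 0.816 with an estimated correlation, including chaperones (-3.17, 31 lower and 4 higher). By the F-test 2195 of 5560 genes differed among the 3 treatments.

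**Figure D3:**
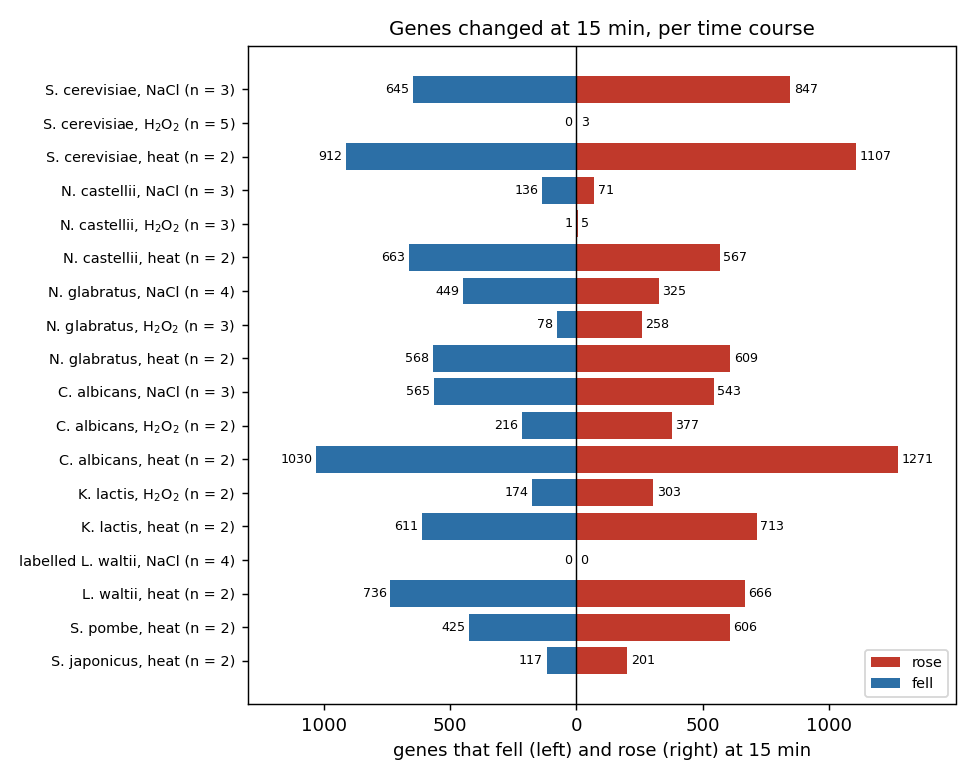
Number of genes that fell (bars to the left) and rose (bars to the right) at 15 min in each of the 18 time courses, with the number of biological replicates. Heat in C. albicans changed the most genes (1271 up, 1030 down), while S. cerevisiae H2O2 (3 and 0) and N. castellii H2O2 (5 and 1) changed few; the NaCl arrays labelled L. waltii show 0 and 0 as labelled, and 553 genes with replicate A turned.

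For the other species the files pair no gene names with the identifiers, so that the gene groups cannot be given. In N. castellii heat moved the largest part of the genes, 1230 of 5517 at 15 min (567 up, 663 down), with Scas_569.8 at 7.56 ± 0.33, Scas_530.5 at 7.17 ± 0.04, Scas_673.19 at -4.43 ± 0.28 and Scas_627.1 at -4.06 ± 0.11 (n = 2). The heat count was 735 without replicate A and 781 without B. NaCl changed 207 of 5581 genes (71 up, 136 down), led by Scas_642.3 (3.64 ± 1.87) and Scas_663.4 (3.52 ± 2.15) and by Scas_719.34 (-2.03 ± 1.53) and Scas_716.69 (-1.99 ± 1.65, n = 3). At 15 min the NaCl array of replicate B had a weak response: without B 559 genes changed (204 up, 355 down), which is also the value on the slide that holds A and C, and 0 without A, without C, with each probe on its own or with the slide as a block. The 60 min NaCl array of B instead had the widest log2 ratios, with an SD of 0.970 against 0.476 in A and 0.376 in C. In H2O2 6 of 5561 genes changed (5 up, 1 down), among them Scas_676.27 (2.72 ± 1.43), Scas_718.67 (1.52 ± 0.76) and Scas_698.36 (-1.53 ± 0.46); without replicate C, weak in this course, 367 did (290 up, 77 down), and 0 without B, without D, with the slide as a block or on the slide with 2 replicates. Median centring gave 55, each probe on its own 14, and 1 gene was called, downward, with processed signals and with the deposited tables. Responses differed between treatments in 1180 of 5553 genes (F-test), with 99 between NaCl and H2O2 (66 with the slide as a random block), 837 between NaCl and heat and 1048 between H2O2 and heat. From 15 to 60 min heat changed 406 genes (166 higher, 240 lower at 60 min; 858 with processed signals, 845 with the deposited tables, 113 without replicate A, 10 without B), and 654 with extreme local backgrounds replaced. For NaCl and H2O2 0 genes differed (946 and 502 at an unadjusted p under 0.05), against 380 without replicate B in NaCl and 258 without C in H2O2; NaCl gave 5 with median centring and 3 with the deposited tables, and H2O2 10 with a random and 1 with a fixed replicate block. At 5, 30 and 60 min 89, 667 and 92 genes had changed in NaCl, 0 (243 at an unadjusted p under 0.05), 373 and 13 in H2O2, and 138, 1721 and 872 in heat, with 966 at 45 min. With extreme local backgrounds replaced, heat gave 302 at 5, 1736 at 45 and 1668 at 60 min.

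CAGL0I10010g of N. glabratus rose under all 3 stresses at 15 min, by 4.55 ± 2.15 in NaCl (n = 4), 5.31 ± 0.32 in H2O2 (n = 3) and 8.82 ± 0.56 in heat (n = 2). NaCl changed 774 of 5211 genes (325 up, 449 down), with CAGL0J04202g at 4.30 ± 2.69, CAGL0K06215g at -2.93 ± 1.64 and CAGL0E05478g at -2.92 ± 1.75. Replicate B responded weakly (SD of log2 ratios 0.21 at 15 min): without it 1187 genes changed, and the slides gave 0 for the 1 that holds B and 1207 for the other. In H2O2 336 of 5153 genes changed (258 up, 78 down), led by CAGL0L05258g (7.54 ± 0.25) and CAGL0C02211g (-2.53 ± 0.15), with 14 called without replicate A, 56 without B and 522 without C or on the slide without C. Rises made up 76.8% of these calls, 63.0% with processed signals and 64.4% with the deposited tables. Heat changed 1177 of 5095 genes (609 up, 568 down), led by CAGL0G03289g (10.78 ± 0.23) and CAGL0J11748g (-3.52 ± 0.39). The 15 min array of replicate A had 43.8% of its red probes above background, and limma called 0 genes without replicate A (which equals leaving out dim arrays), 3 without B and 2 with the slide as a block; rises made up 51.7% of the calls, but 39.5% with processed signals and 40.3% with the deposited tables. Between treatments 1584 of 5154 genes differed (F-test), 361 between NaCl and H2O2, 1140 between NaCl and heat and 984 between H2O2 and heat. From 15 to 60 min 675 genes differed in NaCl (413 higher, 262 lower; 1091 without B, but 0 without A, C or D). In H2O2 91 did (22 higher, 69 lower; 0 without A or B, 496 without C, 149 with median centring, 138 with the deposited tables, 57 with a random and 60 with a fixed replicate block, and 501 with the 30 and 60 min labels of C exchanged). For heat it was 0 (55 at an unadjusted p under 0.05; 1 with the slide as a block and 3 without the 45 min array of A). At 5, 30 and 60 min 97, 110 and 16 genes had changed in NaCl, 0 (247 at an unadjusted p under 0.05), 1091 and 0 (975) in H2O2, and 94, 1200 and 1237 in heat, with 24 at 45 min, where replicates A and B correlated at r = 0.00974 across genes. The 60 min H2O2 array of B was dim, with 31.4% of its probes above background in green and 28.2% in red. The 30 and 60 min labels of H2O2 replicate C may be exchanged, so the H2O2 counts at both times are uncertain. As all time points share 1 spread, the H2O2 counts at 5 and 15 min may be affected too. They were not recomputed with exchanged labels.

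By the number of genes called at 15 min, C. albicans heat was the largest of the 18 courses, with 2301 of 5945 genes (1271 up, 1030 down). In it orf19.822 had a fitted value of 12.56 ± 0.40 with a lower bound of 11.70, its time 0 signal not being above background. The gene orf19.4980 rose by 11.43 ± 0.09, and orf19.4933 (-4.57 ± 0.19) and orf19.5905 (-4.52 ± 0.06) fell most (n = 2). In NaCl 1108 of 5930 genes changed (543 up, 565 down), led by orf19.2344 (9.28 ± 0.38), orf19.3548.1 (8.24 ± 0.79), orf19.4342 (-4.61 ± 0.79) and orf19.3669 (-3.97 ± 0.92, n = 3). In H2O2 593 of 5802 genes changed (377 up, 216 down), led by orf19.3537 (7.54 ± 0.54), orf19.7042 (6.74 ± 0.56), orf19.670.2 (-5.00 ± 0.81) and orf19.2475 (-3.48 ± 0.33, n = 2); 109 genes were called without replicate B and 143 without C, where orf19.670.2 lost its call either way, and the share of rises went from 63.6% to 53.1% with median centring. Between treatments 3051 of 5882 genes differed (F-test), 1180 between NaCl and H2O2, 1963 between NaCl and heat and 2231 between H2O2 and heat. H2O2 and heat have 1 slide each at 15 min, so that treatment and slide cannot be told apart between them. From 15 to 60 min 1390 genes differed in NaCl (705 higher, 685 lower; 606 without B), 1600 in heat (637 higher, 963 lower) and 247 in H2O2 (90 higher, 157 lower; 100 without B, 161 with the replicate as a fixed block, 877 without dim arrays). At 5, 30 and 60 min 556, 450 and 159 genes had changed in NaCl, 39, 1627 and 0 (242 at an unadjusted p under 0.05) in H2O2, and 580, 2185 and 1819 in heat, with 1929 at 45 min. The 60 min H2O2 array of C was dim, with 27.5% of its probes above background in green and 30.0% in red. Its log2 ratios had an SD of 0.106, against 0.857 in B, and correlated with those of B at r = 0.00266. The count of 0 therefore does not show that the response had ended.

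KLLA0A07315g of K. lactis fell under both stresses at 15 min, by -2.96 ± 0.61 in H2O2 and -4.46 ± 0.27 in heat (n = 2 each). In H2O2 477 of 5187 genes changed (303 up, 174 down; 226 without replicate B), led by KLLA0F25938g (7.28 ± 0.26), KLLA0C18931g (6.04 ± 0.27) and KLLA0B00605g (-4.38 ± 0.65). Heat changed 1324 of 5176 genes (713 up, 611 down), led by KLLA0F18909g (9.10 ± 0.27), KLLA0D07634g (8.12 ± 0.13) and KLLA0D04884g (-4.59 ± 0.58). Between H2O2 and heat 1609 of 5174 genes differed, 760 higher in H2O2 and 849 in heat; each treatment has 1 slide, so that treatment and slide cannot be told apart. From 15 to 60 min 1004 genes differed in H2O2 (512 higher, 492 lower; 282 without B) and 584 in heat (315 higher, 269 lower). At 5, 30 and 60 min 47, 812 and 1055 genes had changed in H2O2, and 690, 1428 and 1460 in heat, with 1360 at 45 min.

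Under heat L. waltii changed 1402 of 5052 genes at 15 min (666 up, 736 down), with Kwal_27.10817 at 8.15 ± 0.35, Kwal_55.20703 at 7.58 ± 0.09, Kwal_26.7490 at -5.23 ± 0.28 and Kwal_33.13161 at -5.02 ± 0.24 (n = 2), and 913 genes differed from 15 to 60 min (542 higher, 371 lower; 578 without A). At 5, 30, 45 and 60 min 583, 1565, 659 and 451 genes had changed, with 1054 at 45 min once extreme local backgrounds were replaced. The NaCl arrays labelled L. waltii have the array design of the K. lactis arrays, and across genes replicate A correlates with the mean of B, C and D at r = -0.906 at 15 min. The SD of green over that of red signal across the arrays of a replicate had a median over genes of 3.41 in A, 0.262 in B, 0.261 in C and 0.897 in D. As labelled, 0 of 5131 genes changed (limma; 59 at an unadjusted p under 0.05, and 81, 154 and 18 at 5, 30 and 60 min with 0 called), and 0 differed between 60 and 15 min (1 at an unadjusted p under 0.05). With the sign of A turned, 553 changed (233 up, 320 down). Without A 492 changed (212 up, 280 down), and 571 on the slide with B and C. Turning A gave 822 genes that differ between 60 and 15 min, and leaving it out 655. No identifier is named for this course, since 0 were called.

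The fission yeasts were measured in heat alone. In S. pombe 1031 of 5000 genes changed at 15 min (606 up, 425 down), with SPBC16E9.16c at 8.07 ± 0.08, SPBC3E7.02c at 7.77 ± 0.04, SPBC8E4.01c at -5.74 ± 0.29 and SPAC8E11.10 at -3.89 ± 0.08 (n = 2). From 15 to 60 min 424 genes differed (150 higher, 274 lower), and 547, 908 and 486 had changed at 5, 30 and 60 min. In S. japonicus 318 of 4865 genes changed (201 up, 117 down), with SJAG_04567 at 6.11 ± 1.11, SJAG_03815 at 5.97 ± 0.43, SJAG_04743 at -2.71 ± 0.13 and SJAG_01965 at -2.58 ± 0.03 (n = 2). The count was 557 without replicate B, 516 with processed signals and 537 with the deposited tables. From 15 to 60 min 582 genes differed (203 higher, 379 lower), and 879 without a 15 min technical replicate of B whose ratios correlate at r = 0.00509 across genes with those of the other technical replicates. At 60 min 314 genes had changed. At 5, 30 and 45 min there is 1 replicate, with the spread taken from the other time points. On that assumption 19, 187 and 0 (264 at an unadjusted p under 0.05) had changed, and 197 at 45 min with extreme local backgrounds replaced.

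Biological replicates at 15 min correlated across genes at r = 0.980 to 0.993 for S. cerevisiae NaCl, 0.400 to 0.765 for H2O2 and 0.995 for heat. In the other species the lowest value of a heat course was 0.823, and the NaCl and H2O2 courses lay between -0.884 and 0.980. Genes are not independent replicates, so these values describe the arrays. The median array had 94.4% of its probes above background in green and 95.5% in red.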

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

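Tests of exchanged time labels, of slower cultures, of the background fit and of processing by the extraction software, and the runs with turned or exchanged arrays, were chosen after the results were seen.

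The first pattern concerns the NaCl arrays labelled L. waltii, which have the array design and identifiers of the K. lactis arrays. Across 5322 genes their median time 0 signal correlated with that of the arrays labelled K. lactis at Spearman's rho = 0.948, against 0.898 between the H2O2 and heat arrays labelled K. lactis. Probes above background made up 95.4% on the 16 arrays labelled L. waltii and 94.9% on the 18 labelled K. lactis, which argues against RNA of another species hybridizing poorly to this design. A candidate explanation is therefore a wrong species label; single arrays had rho from 0.00914, on an array with failed signal, to 0.947. No biological explanation was tested.

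The second pattern is replicate A of the same course, which ran opposite to replicates B, C and D. Processing by the extraction software is argued against, since the correlation of A with the mean of the others at 15 min was already -0.832 in unprocessed channels and -0.906 after loess. The green channel varied 3.41 times as much as the red across the arrays of A (median over genes of the SD ratio), against 0.262 in B, 0.261 in C and 0.897 in D, as dyes exchanged in A would give. Were B and C the turned ones, their ratios would lie above 1, so an exchange in A may be the cause. Without its 60 min array, which has failed signal, D had 0.617. With A turned 553 genes changed (233 up, 320 down), without A 492, and 470 were called in both. At 5, 30 and 60 min turning A gave 354, 328 and 235 genes, and leaving it out 391, 353 and 0 (limma; 1094 at an unadjusted p under 0.05).

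The third pattern is a set of arrays that matched another time point of the other replicates better than their own. In N. castellii heat replicate B at 45 and 60 min, the match came with the background fit of the processing used here. Once extreme local backgrounds were replaced, the mean correlation across genes with the other replicate at the same times went from 0.835 to 0.981, against 0.968 with exchanged labels, and the 60 min array matched 60 min best. The 45 min array then had r = 0.972 with both times, and with processed signals 0.968 with 45 and 0.969 with 60 min, so that an exchange and a slower culture cannot be told apart from correct labels. Between 60 and 15 min 654 genes differed with these backgrounds replaced, 858 with processed signals and 845 with the deposited tables, against 406. In N. glabratus H2O2 replicate C, the 60 min array matched 30 min best (r = 0.982). Without the dim 60 min array of B, the 30 min array, which was not picked for its match, had r = 0.830 with 60 min, where 1 replicate was left, against 0.432 with 30 min. Exchanged labels may thus be the cause. With the dim array kept, the 30 min array matched 30 min (0.432) about as well as 60 min (0.407), and so it did with processed signals (0.418 and 0.397). A slower culture, which would leave these matches in order, therefore stays open. The background fit is argued against, since the mean correlation stayed at 0.295 with backgrounds replaced. In S. japonicus heat, technical replicate 3 of B at 15 min correlated at r = 0.932 with the 60 min array of B, at 0.967 with its 45 min array with backgrounds replaced, and at 0.00509 with the other technical replicates, also with backgrounds replaced, which argues against the background fit. The other technical replicates correlated with each other at 0.828. A wrong label stays open for this array, and no biological explanation was tested beyond culture speed.

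A replicate far from the others was found in 9 of 121 groups of named genes, where chance gives about 1 in 20. In N. glabratus NaCl replicate B lay far from the others in CAGL0I10010g (1.35), CAGL0J04202g (0.27), CAGL0K06215g (-0.49) and CAGL0E05478g (-0.30). In S. cerevisiae H2O2 at 15 min these were GPD1 in replicate B (-0.14), RPP1A in F (0.16), RRP12 in D (0.52), RPC17 in A (-0.90) and PDC1 in F (0.51).

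Responses at 60 and 15 min differed in 714 genes for S. cerevisiae NaCl and 939 for heat (1 replicate at 60 min), 406 for N. castellii heat, 675 for N. glabratus NaCl and 91 for H2O2. They differed in 1390 genes for C. albicans NaCl, 247 for H2O2 and 1600 for heat, 1004 for K. lactis H2O2 and 584 for heat, 913 for L. waltii heat, 424 for S. pombe and 582 for S. japonicus. Responses at 15 min differed between treatments in 2195 genes of S. cerevisiae, 1180 of N. castellii, 1584 of N. glabratus, 3051 of C. albicans and 1609 of K. lactis. For S. cerevisiae 12 gene lists differed between NaCl and H2O2, 6 between NaCl and heat and 13 between H2O2 and heat. With an estimated correlation 1, 0 and 0 of these kept their call.

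Chance was set against these counts with other splits of the same arrays. Between NaCl and H2O2 in S. cerevisiae 1 of 56 splits, the real one, gave as many as 1382 genes, and the highest other, which follows the slides, gave 2. This is the lowest share that 56 splits can give, and it was not adjusted over the split tests. It argues against chance but does not exclude it. The real split follows the slides too, and NaCl replicates A and B lie on another array design. No slide holds 15 min arrays of more than 1 treatment, but here NaCl spans 2 slides and H2O2 5, and with the slide as a random block 1374 genes differed. In N. castellii this block gave 66 genes between NaCl and H2O2 and in N. glabratus 351. Treatment and slide cannot be told apart between H2O2 and heat in C. albicans and K. lactis, where each treatment has 1 slide. In S. cerevisiae the NaCl arrays were also extracted in another software version than the H2O2 arrays. In N. glabratus chance cannot be excluded between these treatments, as 2 of 35 splits gave at least the real 361 genes and the highest other 768; that split sets the weak NaCl replicate B with the H2O2 arrays, so it points to a structure of the samples. Nor can it for N. glabratus NaCl between 60 and 15 min, where 2 of 35 splits gave at least the real 675 genes and the highest other, which exchanges arrays of the weak replicate B and of A, gave 697. S. cerevisiae H2O2 had a real count of 0 and 0 as the highest other, so that all 100 splits drawn were as large. For the NaCl arrays labelled L. waltii all 35 splits were at least as large as the real 0, and the highest other, 548, points to the structure given by replicate A.

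With 10 splits the share cannot fall under 0.05 between 60 and 15 min in S. cerevisiae NaCl (1 split as large, real 714, highest other 0), N. glabratus H2O2 (1 split, 91 and 0), C. albicans NaCl (1 split, 1390 and 0), N. castellii NaCl (10 splits, 0 and 91) and N. castellii H2O2 (10 splits, 0 and 0), or between NaCl and H2O2 in N. castellii (1 split, 99 and 86). The 91 genes of a split in N. castellii NaCl, against a real count of 0, point to a structure of the samples. That split exchanges the 15 and 60 min arrays of replicate B. At 15 min the SD of log2 ratios was 0.211 in B, 0.647 in A and 0.663 in C, and at 60 min it was 0.970, 0.476 and 0.376. Whether the time labels of B were exchanged was not tested.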

How the results depend on the processing

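Chosen after the results were seen were the runs without dim arrays, on 1 slide, with turned or exchanged arrays, without a technical replicate or the 45 min arrays of 1 culture, with extreme local backgrounds replaced, and, between pairs of treatments, with the slide as a random block or on 1 array design. For each value that moved, the cause was not tested unless it is given.

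Without a fold threshold, which by construction calls more genes, the counts at 15 min were 4422 for S. cerevisiae NaCl, 12 for H2O2 and 4254 for heat, 535 for N. castellii NaCl and 3256 for heat, 3521, 1167 and 2798 for N. glabratus NaCl, H2O2 and heat, and 3340, 1126 and 5227 for C. albicans. They were 1829 for K. lactis H2O2 and 4090 for heat, 3908 for L. waltii heat, 4174 for S. pombe and 1599 for S. japonicus. Median centring gave 1 for S. cerevisiae H2O2 and 55 for N. castellii H2O2 at 15 min, and between 60 and 15 min 463 for S. cerevisiae NaCl, 5 for N. castellii NaCl and 149 for N. glabratus H2O2. Processed signals gave 1 for N. castellii H2O2 and 516 for S. japonicus at 15 min, and 858 for N. castellii heat between 60 and 15 min. The deposited tables gave 1 and 537 for the same 15 min counts, and between 60 and 15 min 3 for N. castellii NaCl, 845 for its heat course and 138 for N. glabratus H2O2.

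With the slide as a block the 15 min counts were 0 for N. castellii NaCl, 0 for its H2O2 course and 2 for N. glabratus heat, and 1 gene differed between 60 and 15 min in N. glabratus heat. Each probe on its own gave 0 and 14 for N. castellii NaCl and H2O2. Arrays of 1 slide gave 559 for N. castellii NaCl and 0 for H2O2, 0 and 1207 for N. glabratus NaCl, 522 for its H2O2 course and 571 for the NaCl arrays labelled L. waltii. Runs without dim arrays gave 6 for S. cerevisiae H2O2 and 0 for N. glabratus heat, where 1 array was left, and between 60 and 15 min 1 for S. cerevisiae H2O2 and 877 for C. albicans H2O2. Turning replicate A labelled L. waltii gave 553 at 15 min and 822 between 60 and 15 min; exchanged time labels gave 920 for N. castellii heat and 501 for N. glabratus H2O2. Extreme local backgrounds replaced gave 654 for N. castellii heat between 60 and 15 min. Without technical replicate 3 S. japonicus gave 879, and without the 45 min arrays of A N. glabratus heat gave 3.

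The replicate letter was used as a block, on the assumption that arrays of 1 letter in a course share a culture. As a random block it left the 17 fitted 15 min counts within 1.5 times (1492 for S. cerevisiae NaCl, 209 for N. castellii NaCl, 354 for N. glabratus H2O2). Between 60 and 15 min it moved 2 of 17, N. castellii H2O2 (10) and N. glabratus H2O2 (57), and a fixed block moved 4 of 18: 536 for S. cerevisiae heat, 1 for N. castellii H2O2, 60 for N. glabratus H2O2 and 161 for C. albicans H2O2. In C. albicans NaCl, where letters go together across all time points, the blocks gave 1504 and 1506 against 1390.

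Leaving out 1 replicate in turn gave at 15 min 0 to 3 genes for S. cerevisiae H2O2, 0 to 559, 0 to 367 and 735 to 781 for N. castellii NaCl, H2O2 and heat, and 614 to 1187, 14 to 522 and 0 to 3 for N. glabratus. It gave 109 to 143 for C. albicans H2O2, 226 to 583 for K. lactis H2O2, 0 to 492 for the NaCl arrays labelled L. waltii and 227 to 557 for S. japonicus. Between 60 and 15 min the ranges were 0 to 1 for S. cerevisiae H2O2, 0 for its heat course (1 setting), 0 to 380, 0 to 258 and 10 to 113 for N. castellii NaCl, H2O2 and heat, and 0 to 1091 and 0 to 496 for N. glabratus NaCl and H2O2. They were 606 to 1503 and 100 to 173 for C. albicans NaCl and H2O2, 282 to 899 for K. lactis H2O2, 0 to 655 for the NaCl arrays labelled L. waltii and 578 to 661 for L. waltii heat. For lists the adjusted p ranged from 0.0429 to 0.139 for ergosterol synthesis in NaCl, and in H2O2 from 0.0326 to 0.0795 for RNA polymerase I and III and from 0.00389 to 0.0771 for amino acid biosynthesis.

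With an estimated correlation no list kept its call at 15 min against time 0. With few residual degrees of freedom there, this leaves open whether a list shifted. Glycerol and ion homeostasis kept its call between NaCl and H2O2 (adjusted p = 0.00541), in a fit with more of them. In NaCl the adjusted p was 0.281 for ribosome biogenesis, RNA polymerase I and III, glycerol and ion homeostasis and autophagy, 0.471 for antioxidants, 0.483 for general stress and for trehalose and glycogen, 0.508 for chaperones, the pentose phosphate pathway, the proteasome, respiration, glycolysis and amino acid biosynthesis, and 0.796 for ribosomal proteins. In H2O2 it was 0.281 for glycolysis, 0.483 for the mitochondrial ribosome and histones, 0.508 for ribosomal proteins, 0.626 for amino acid biosynthesis and 0.705 for RNA polymerase I and III. In heat it was 0.281 for antioxidants and autophagy, 0.356 for the pentose phosphate pathway and the iron regulon, 0.483 for glycerol and ion homeostasis, 0.508 for chaperones, general stress and trehalose and glycogen, 0.582 for ribosome biogenesis, 0.611 for RNA polymerase I and III and the proteasome, 0.624 for respiration, 0.705 for the mitochondrial ribosome and glycolysis, and 0.921 for ribosomal proteins. By scaling, median centring gave 0.132 for ribosomal proteins and 0.110 for the proteasome in NaCl, and in H2O2 0.0476 for the pentose phosphate pathway and 0.257 for histones, whose median turned to 0.13. Processed signals gave 0.847 for ribosomal proteins in H2O2, whose median turned to -0.01, and in heat 0.285 for ribosomal proteins and 0.0490 for amino acid biosynthesis. Over 13 settings the ribosomal protein median in H2O2 ran from -0.03 to 0.59. The deposited tables gave 0.499 for glycolysis in NaCl, 0.665 for ribosomal proteins in H2O2, and in heat 0.307 for ribosomal proteins and 0.0544 for glycerol and ion homeostasis.

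Of the values apart from those without a replicate, 137 of 173 counts at 15 min, 128 of 150 between 60 and 15 min and 38 of 38 between treatments stayed within 1.5 times, 448 of 494 list results kept their direction and side of the threshold, and so did 2587 of 2631 values of named genes (36 lost a call, 8 gained it, 0 turned). Leaving out a replicate, this held for 26 of 48, 27 of 45, 38 of 38, 186 of 190 and 1049 of 1102. Leaving out the filter on dim probes changed none of these calls. With the slide as a random block, all 19 lists kept their call or its absence in each pair of treatments. On 1 design (1 NaCl replicate) 18 of 19 did in each pair, the others being the proteasome between NaCl and H2O2 (adjusted p = 0.123), RNA polymerase I and III between NaCl and heat (0.0633) and the pentose phosphate pathway between H2O2 and heat (0.0808). Counts between treatments ranged, without a replicate, from 2030 to 2274 in S. cerevisiae, 880 to 1363 in N. castellii, 1304 to 1977 in N. glabratus, 2675 to 3239 in C. albicans and 1488 to 1751 in K. lactis. No value could be had for S. cerevisiae heat between 60 and 15 min without replicate A, nor for S. japonicus with a random replicate block, on 1 slide, or between 60 and 15 min without A or B.

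Processed signals shifted the median of all genes on single arrays by up to -0.36 in S. cerevisiae H2O2 and -0.22 in N. glabratus heat and L. waltii heat, and reported changes are relative to each array's own centre. Signal over background limits the fitted values of genes without time 0 signal, for which lower bounds are given, and the 7 arrays on which under 50% of probes passed in a channel; the dimmest, at 60 min in replicate D labelled L. waltii, had 2.04% above background in green.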

Other observations

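At time points outside the main comparison, chosen for testing after the 15 min results were seen, further gene groups moved in S. cerevisiae. Proteasome genes rose in 25 of 42 cases at 30 min in NaCl (median 1.05, camera adjusted p = 1.02e-08; adjusted p = 0.432 with an estimated correlation) and in 0 at 60 min (median 0.24). Sulphur assimilation genes rose in 11 of 25 cases at 30 min (1 fell; median 0.90) and in 15 at 60 min (2 fell; median 1.42, adjusted p = 6.17e-05; adjusted p = 0.405 with an estimated correlation). Respiration and TCA cycle genes rose in 29 of 46 cases at 30 min and 32 at 60 min. At 30 min in NaCl 18 of 62 amino acid biosynthesis genes fell and 2 rose, and the counts adjusted over the list alone were the same for all of these.

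In heat, iron regulon genes rose in 9 of 24 cases by 5 min and chaperones in 23 of 40 (1 fell). Histone genes fell in 4 of 11 cases at 30 min in heat and in 4 of 11 at 60 min in H2O2 (median -0.84, adjusted p = 1.54e-04; adjusted p = 0.372 with an estimated correlation), and ribosomal protein genes in 14 of 137 at 60 min in H2O2 (median -0.30). The H2O2 counts at 60 min rest on a spread shared by all time points, although replicates differed widely at 60 min. None of the list calls against time 0 at any time point of the S. cerevisiae courses held with an estimated correlation, with extreme local backgrounds as processed or replaced.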
